A study of Homo sapiens with 18 samples.

How the data were processed

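The study measured messenger RNA by sequencing in 3 human lymphoma lines, SUDHL6, SUDHL4 and Farage, under a BCL6 inhibitor or DMSO, with 3 libraries in each of 6 groups. Cells were grown in RPMI1640 medium with 10% fetal bovine serum and the libraries were made with an Illumina mRNA kit, per the labels. The labels give 12 h in the titles and 24 h in the source names, and which holds is open. The compound, its dose, the strandedness and whether replicates were separate cultures are not given in the sources used here, so each p measures the spread between samples.

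The authors deposited a table of FPKM values, 1 per library and locus, for 34410 loci. Their notes name CASAVA 1.8, TopHat2, Cufflinks and the genome build hg19. The versions of TopHat2 and Cufflinks, the annotation and any further scaling are not given in the sources used here. The sheet name points to fold changes and p-values, but the table held only values per library, so the plan to copy such columns had nothing to copy. FPKM sums ran from 1130000 to 1548000 FPKM per library. Counts were not in the table. Relative depth was read from the whole-read steps of FPKM at unnamed loci of 56 bp, within a tolerance of 0.02, in 16 libraries, and spanned 0.691 to 1.15 of the median. Both SUDHL6 replicate 3 libraries had no such values. Since counts are unknown, no counting interval or detection floor is given.

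Of the loci 26004 carried a gene name and 8406 did not. The unnamed loci, 5.72 to 19.1% of the FPKM per library, were left out because they cannot be named. Loci that merge several genes (1681), loci sharing a name (615 tested), 26 names turned into dates and 1249 loci on alternate contigs such as the HLA haplotypes stayed in the tests and could not be resolved further. Genes with at least 1 FPKM in at least 3 of the 18 libraries were kept, 12201 in all, among them 1384 merged loci, 480 small RNA loci and 15 date names.

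Values were taken as log2(FPKM + 1) and fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group and an empirical Bayes prior with an intensity trend. The comparisons were inhibitor against DMSO in each line, the mean of the 3 within-line differences and the moderated F test of the difference between lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Overlap of calls was compared with that of independent lists and tested with Fisher's exact test across genes, whose p lay below what the software resolves. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and plots with matplotlib 3.10.9.

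The comparisons, tests, 28 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The lists cover BCL6 direct targets, BCL6 corepressors, p53 targets, DNA damage, S phase, G2 and mitosis, NF-kB targets, the interferon response, MHC class II, germinal centre, plasma cell and B cell receptor genes, immediate early genes, cholesterol synthesis, the integrated stress response, endoplasmic reticulum chaperones, heat shock, NRF2, the aryl hydrocarbon receptor, MYC and ribosome biogenesis, glycolysis and hypoxia, BCL2 family, NOTCH, histones, T and NK cell, monocyte, fibroblast and epithelial, and mitochondrially encoded genes. Of their 616 genes 503 matched a locus, 6 of them by an older symbol, 99 lay only in loci shared with other genes and 14 had no locus. Lists with fewer than 3 measured genes were not tested as lists, which left 25. Camera with a preset correlation of 0.01 compared each list with the other genes, and camera with an estimated correlation and fry were alternatives. List p-values were adjusted within a comparison.

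Named genes are BCL6, the 10 largest increases and 10 largest decreases of the average with the same sign in all lines, the 5 of each kind per line with separated groups, the 6 smallest p of the difference, each with a mean of at least 5 FPKM, and up to 4 members of each list. Small RNA, LOC and LINC symbols and merged loci were not eligible. The text leaves out 3 genes that this rule selects, which stayed in all tests and counts. A gene that fell under several of these was described under each. Members named from 7 lists added after seeing the data (lysosome, autophagy, mitochondrial and cytosolic ribosomal proteins, proteasome, respiratory complex I, tubulins and actins) were chosen after their values were seen.

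The method was tested on simulated data with the same layout, in which 200 of 12201 genes were changed. Of changes of 1 on the log2 scale 90.1, 90.1 and 89.2% were found in the 3 lines and 94.6% on average, and of changes of 0.5 it found 55.1, 57.3, 52.8 and 85.4%. False calls made up 6.9, 4.4, 3.9 and 4.2% of calls. The simulated noise was independent, with 1 SD per gene for all libraries. It held neither the wider spread of SUDHL6 nor the shift of its replicate 3 libraries, and far fewer genes were changed than were called in the data. These shares thus describe that setting and may not hold for the data. Whether replicate numbers pair the samples was checked by correlating residuals of inhibitor and DMSO libraries. In SUDHL6 the same numbers gave 0.31, 0.37 and 0.66, inhibitor 1 with DMSO 2 gave 0.32, inhibitor 2 with DMSO 1 gave 0.27, and replicate 3 against the others lay between -0.43 and -0.51. Replicate 3 thus stands apart in both groups and numbers 1 and 2 were not seen to pair, and blocked values are given. SUDHL4 (-0.03, 0.06 and -0.06) and Farage (0.07, -0.04 and 0.08) showed no pairing.

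Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, limma without trend or with a robust prior, a replicate block, each library left out, stricter thresholds and fits within a line. Chosen after seeing the data were the runs without both SUDHL6 replicate 3 libraries, without small RNA loci, with unnamed loci, with a trend over GC content and transcript length removed, the tests of list differences between lines, these and the F test of named genes with a pseudocount of 0.1, and the estimated correlation with a block or without those 2 libraries.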

Results

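Messenger RNA was sequenced from 3 established human lines of diffuse large B cell lymphoma of the germinal centre type, SUDHL6, SUDHL4 and Farage. Each line was treated with an inhibitor of BCL6, the transcriptional repressor of germinal centre B cells, or with the solvent DMSO. Each of the 6 groups held 3 libraries, 18 in all. The question the labels give is what the inhibitor does to transcript levels in these lines, and the sample titles give 12 h of treatment where the source names give 24 h. The values were FPKM, and their sums ran from 1130000 to 1548000 FPKM per library. Small RNA loci held 22.9 to 51% of a library's sum and its highest locus 10.6 to 45.2%, so the sums are not totals of messenger RNA. No read counts stood in the table, so the depth is unknown in absolute terms. Relative depth, read from the whole-read steps of the values at short loci, spanned 0.691 to 1.15 of the median in the 16 libraries that allowed it. It was lower in treated than in DMSO libraries of SUDHL6 (0.775 and 0.821 against 1.03 and 1.04, replicates 1 and 2) and of SUDHL4 (0.845, 0.861 and 0.691 against 0.998, 1.15 and 1.07). In Farage it was 1.00, 0.869 and 0.999 against 1.11, 1.04 and 1.01. There too every treated library lay below every DMSO library, with treated replicates 1 and 3 within 0.02 of DMSO replicate 3. Pearson's r across genes, which are not independent replicates, lay between 0.957 and 0.973 for pairs of libraries within the SUDHL4 and Farage groups. In SUDHL6, replicates 1 and 2 correlated at 0.962 in DMSO and 0.947 under the inhibitor, whereas replicate 3 reached 0.909 and 0.895 at most. The first 3 principal components carried 32, 22.1 and 18.8% of the variance.

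BCL6 itself, on chromosome 3 from 187388558 to 187463515 of hg19, fell in SUDHL4 and passed the test in neither of the other lines. In SUDHL4 it went from 131 ± 7.84 FPKM (SD, n = 3) in DMSO to 72.3 ± 0.416 FPKM (SD, n = 3) under the inhibitor. That was a log2 fold change of -0.85 with a Benjamini-Hochberg adjusted p = 1.24e-05 in limma, with all 3 treated libraries below all 3 DMSO libraries. SUDHL6 held 82.2 ± 15.2 FPKM in DMSO and 71.7 ± 11.8 FPKM under the inhibitor (log2 fold change -0.19, adjusted p = 0.161). Farage held 53.8 ± 0.611 and 61.9 ± 2.34 FPKM (log2 fold change 0.20, adjusted p = 0.142), with all 3 treated libraries above all 3 DMSO libraries. The fit gave BCL6 the same SE in each line (0.11), and the SUDHL6 groups had the widest SD. The BCL6 response differed between the lines (F test, adjusted p = 0.000369), and its mean over the lines was -0.28 (SE 0.07, adjusted p = 0.00125). With the replicate number as a block, BCL6 passed the test in SUDHL6 (-0.19, adjusted p = 0.0131) and in Farage (0.20, adjusted p = 0.0104). Without SUDHL6 inhibitor replicate 2 the SUDHL6 change was -0.32 with adjusted p = 0.0191. Over all 30 alternatives the adjusted p of BCL6 ran from 0.0131 to 0.721 in SUDHL6 and from 0.0104 to 0.288 in Farage.

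On log2(FPKM + 1) averaged over the 3 lines, ATF3 led the 10 largest increases and PTPN6 the 10 largest decreases. The order depends on the pseudocount at low values. OSGIN1 was at 0.0190, 0.913 and 0.0523 FPKM in DMSO of SUDHL6, SUDHL4 and Farage. ATF3, a stress-induced transcription factor, rose by a log2 fold change of 4.05 (SE 0.24), and SQSTM1, the autophagy receptor p62, by 3.88 (SE 0.21). DDIT3, the stress factor CHOP, rose by 3.58 (SE 0.25). The other genes among the 10 largest increases were HSPA1B (3.93), RGS1 (3.89), OSGIN1 (3.88), SLC7A11 (3.78), SLAMF7 (3.75), the long noncoding RNA LUCAT1 (3.60) and LY9 (3.59). SQSTM1 went from 26.4 ± 3.17 to 656 ± 190.1 FPKM in SUDHL6, from 45.8 ± 36.9 to 597 ± 78.9 in SUDHL4 and from 78.6 ± 3.66 to 712 ± 47.1 in Farage (each SD, n = 3). PTPN6, which encodes the phosphatase SHP-1, fell by 2.86 (SE 0.15) and SIT1 by 2.78 (SE 0.16). PTPN6 went from 18.2 ± 6.76 to 2.97 ± 1.63 FPKM in SUDHL6, from 139 ± 15.2 to 11.1 ± 0.658 in SUDHL4 and from 194 ± 5.83 to 28.4 ± 3.50 in Farage. ELL3 (-2.66), CDCA7 (-2.66), TRAF3IP3 (-2.52), SPC24 (-2.51), VPREB3 (-2.51), MRM1 (-2.50), the B cell transcription factor POU2F2 (-2.47) and RSAD1 (-2.44) followed. The adjusted p of the average lay between 2.8e-13 and 3.81e-08 for these 20 genes. All 20 had the same direction in each line, which the rule that named them requires. Their adjusted p within a line was at most 0.000627 (RGS1 in Farage). The average that named them is the mean of these same within-line effects, so this is no separate support.

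In limma 4350 of the 12201 tested genes were higher and 5481 lower on average under the inhibitor, which is 35.7 and 44.9%. With an absolute log2 fold change of at least 0.5 the counts were 2442 and 3224. The median log2 fold change of all tested genes was -0.08. Folds were computed on log2(FPKM + 1), which understates those of genes with low values.

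**Figure D1:**
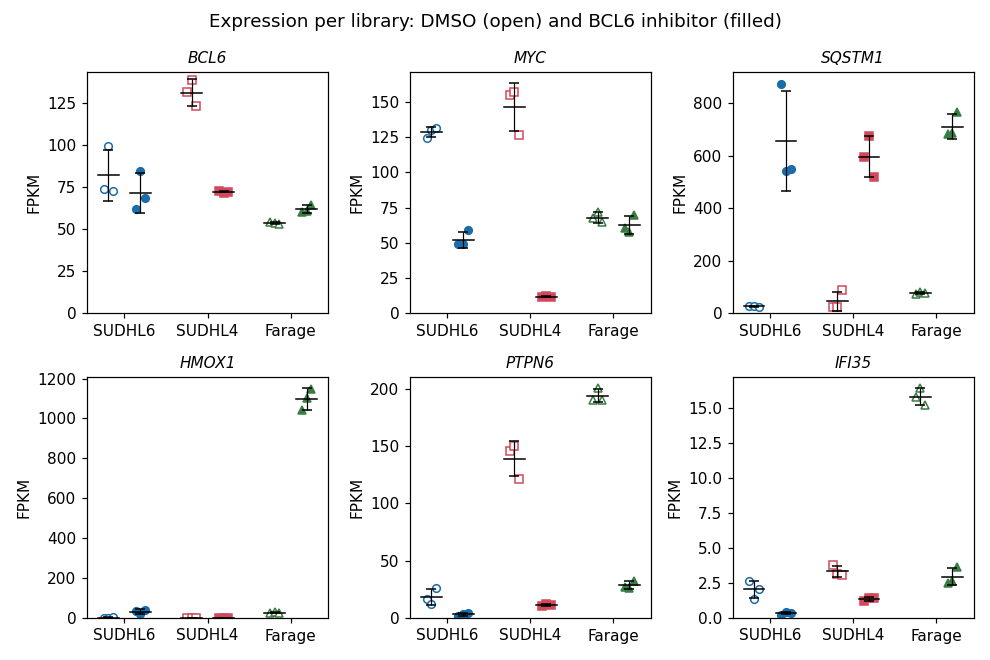
FPKM of BCL6, MYC, SQSTM1, HMOX1, PTPN6 and IFI35 in each library of SUDHL6, SUDHL4 and Farage, with open points for DMSO and filled points for the BCL6 inhibitor, and the mean and SD of each group of 3 libraries. BCL6 is lower under the inhibitor in SUDHL4 (131 against 72.3 FPKM), HMOX1 reaches 1098 FPKM in treated Farage, and 1 DMSO library of SUDHL4 lies above the other DMSO libraries for SQSTM1, at 88.4 FPKM.

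Genes of the integrated stress response rose together. Of its 22 measured members 21 rose and none fell on average, among them SLC7A11, the cystine transporter, DDIT3 and CTH (3.09), an enzyme of cysteine synthesis (camera adjusted p = 3.68e-08, adjusted p = 0.215 with an estimated correlation). All 17 measured genes of the heat shock response rose, including HSPA1B, the cochaperone BAG3 (3.13), DNAJB1 (2.89) and CHORDC1 (2.19) (adjusted p = 4.3e-07, and adjusted p = 0.322 with an estimated correlation). HSPA1A and HSPA1B lie in a single locus span on chromosome 6 from 31777396 to 31800310 and are near-identical paralogs, so how their reads were divided is uncertain. Among 14 genes of the oxidative stress (NRF2) response 11 rose and none fell, including OSGIN1, SLC7A11, HMOX1 (3.12), which encodes heme oxygenase, and SRXN1 (2.71) (adjusted p = 0.000252, and adjusted p = 0.322 with an estimated correlation). The 6 measured aryl hydrocarbon receptor targets all rose on average, led by the amino acid transporter SLC7A5, TIPARP (1.55), NFE2L2 (1.46) and CYP1B1 (0.43) (adjusted p = 0.00317, and adjusted p = 0.196 with an estimated correlation). In SUDHL6 alone 3 of the 6 were higher, and CYP1B1 rose in Farage (1.31) and was near 0 FPKM in SUDHL6 (-0.01, adjusted p = 0.906) and SUDHL4 (0.00, adjusted p = 0.978). In the glycolysis and hypoxia list 14 of 17 genes rose and 2 fell, with VEGFA (2.78), the mitophagy receptor BNIP3L (2.05), the demethylase KDM3A (2.03) and P4HA1 (1.95) rising most (adjusted p = 0.000938, and adjusted p = 0.325 with an estimated correlation). In SUDHL6 alone this list had 8 genes higher and 6 lower, with a median of 0.314 and no call (adjusted p = 0.52), against medians of 0.912 in SUDHL4 and 1.468 in Farage.

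Immediate early genes split, with 17 of 23 higher and 4 lower. ATF3, DUSP5 (3.45), FOS (3.10) and the phosphatase DUSP1 (2.37) rose, whereas MYC (-1.64) fell (adjusted p = 0.00442, and adjusted p = 0.322 with an estimated correlation). In SUDHL4 the list had 9 genes higher and 5 lower, with a median of 0.048 and no call (adjusted p = 0.382). Of 9 replication-dependent histones 8 rose, including HIST1H4C (1.94), HIST1H2BC (1.60), HIST1H2AC (1.46) and HIST1H2BJ (1.45) (adjusted p = 0.00582, and adjusted p = 0.322 with an estimated correlation). Their near-identical sequences and scarce polyadenylation leave those values uncertain. In SUDHL4, DMSO replicate 3 stood above the other DMSO libraries for induced genes: SQSTM1 was at 23.8, 25.2 and 88.4 FPKM and DDIT3 at 19.1, 17.9 and 76.6 FPKM in DMSO replicates 1, 2 and 3.

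Genes of proliferation and growth fell. Of 28 genes of S phase and DNA replication 26 fell and none rose, including the replication factor GINS1 (-1.76), UHRF1 (-1.75) and thymidylate synthase TYMS (-1.74). Camera gave this list an adjusted p = 0.000231, and adjusted p = 0.546 with an estimated correlation. Among 23 genes of G2 and mitosis 22 fell and none rose, with the mitotic kinase AURKB at -1.99, CDC20 at -1.72, TOP2A at -1.69 and KIF20A at -1.61. Its adjusted p = 0.00442 became adjusted p = 0.609 with an estimated correlation. The DNA damage checkpoint and repair list held 19 of 23 genes lower and 2 higher, with CLSPN (-1.24), FANCI (-1.23), NBN (-1.09) and the helicase BLM (-1.04) falling most (adjusted p = 0.0127, and adjusted p = 0.546 with an estimated correlation). MYC and genes of ribosome biogenesis fell in 17 of 19 cases, led by MYBBP1A (-1.91), RRP9 (-1.82), the spermidine synthase SRM (-1.65) and MYC, and none rose (adjusted p = 5.01e-05, and adjusted p = 0.325 with an estimated correlation). In SUDHL6 the treated libraries spread widely in these groups, with TOP2A at 8.70, 31.4 and 54.0 FPKM in replicates 1, 2 and 3, against 70.5, 69.6 and 96.2 FPKM in DMSO.

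B cell programmes fell as well. In the germinal centre list 16 of 22 genes fell and 4 rose, with ELL3, VPREB3, PAX5 (-1.97), the B cell identity factor, and MYB (-1.39) falling most (adjusted p = 0.0127, and adjusted p = 0.322 with an estimated correlation). B cell receptor signalling had 16 of 22 genes lower and 3 higher, among them PTPN6, the adaptor BLNK (-1.56), the lipid phosphatase INPP5D (-1.45) and FCGR2B (-1.20). PTPN6, INPP5D and FCGR2B are known to restrain the receptor and BLNK to carry its signal (adjusted p = 0.00816, and adjusted p = 0.354 with an estimated correlation). MHC class II presentation had 8 of 10 genes lower and 1 higher, including HLA-DMB (-2.23), the class II transactivator CIITA (-1.17), HLA-DOA (-0.92) and RFXANK (-0.91) (adjusted p = 0.0348, and adjusted p = 0.325 with an estimated correlation). The type I interferon list had 15 of 21 genes lower and 2 higher, with IFI35 (-1.39) and ISG15 (-1.03) falling and IRF7 (0.85) rising (adjusted p = 0.0191, and adjusted p = 0.202 with an estimated correlation). Its call was lost with a pseudocount of 0.1 (adjusted p = 0.0647), and its camera adjusted p ran from 0.0166 with median-ratio scaling to 0.351 with an estimated correlation and the replicate block. Fry, which does not compare a list with other genes, gave adjusted p = 9.49e-14.

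The list of BCL6 direct targets from the literature, genes that BCL6 is held to repress, moved both ways. Of 43 measured members 23 rose, 9 fell and 11 did not pass the test (adjusted p = 0.024 for a rise, and adjusted p = 0.268 with an estimated correlation). Within SUDHL4 it had 20 higher and 9 lower (median 0.306, adjusted p = 0.107) and within Farage 16 higher and 12 lower (median 0.082, adjusted p = 0.246). The tests of the difference found none from SUDHL6 (adjusted p = 0.635 for SUDHL4 and 0.602 for Farage) or between SUDHL4 and Farage (0.709). DUSP5 (3.45), CDKN1A (1.97), which encodes the cell cycle inhibitor p21, and the chemokine receptor CXCR4 (1.90) rose. PTPN6 and MYC fell. CXCR4 went from 97.6 ± 19.1 to 502 ± 215.9 FPKM in SUDHL6, from 36.9 ± 4.90 to 89.6 ± 7.71 in SUDHL4 and from 27.5 ± 0.223 to 126 ± 7.77 in Farage (SD, n = 3). BCL6 corepressor genes, with 12 higher and 12 lower of 24, gave no call as a list (adjusted p = 0.495). RYBP (1.96), HDAC9 (-0.95), CTBP2 (0.91) and SKP1 (0.85) had the largest changes there.

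Other lists gave no call on average although single members changed. The p53 targets had 12 of 24 genes higher and 9 lower (adjusted p = 0.461), with PMAIP1 (2.31), SESN2 (2.19) and CDKN1A higher and AEN (-1.62) lower. The NF-kB targets had 3 of 18 higher and 5 lower (adjusted p = 0.819), with the chemokine receptor CCR7 (2.57) and CCL3 (0.91) higher and CD40 (-1.22) and BCL2A1 (-1.01) lower. CCL3 rose in Farage (2.72) and did not pass the test in SUDHL6 (0.43, adjusted p = 0.124) or SUDHL4 (-0.42, adjusted p = 0.129), nor did BCL2A1 in SUDHL6 (-0.11, adjusted p = 0.832). Plasma cell genes had 6 of 13 higher and 6 lower (adjusted p = 0.581), with SLAMF7, IRF4 (1.64) and XBP1 (1.41) higher and TNFRSF17 (-1.84), the receptor BCMA, lower. Cholesterol synthesis had 11 of 20 higher and 7 lower (adjusted p = 0.251), with INSIG1 (0.95) and MSMO1 (0.84) higher and ACAT2 (-1.12) lower. Among chaperones of the endoplasmic reticulum 9 of 16 were higher and 7 lower (adjusted p = 0.282), with DNAJC3 (1.61), SEL1L (1.54), DNAJB9 (1.45) and XBP1 higher. The BCL2 family and apoptosis list had 8 of 18 higher and 7 lower (adjusted p = 0.524), with PMAIP1 higher and BCL2L1 (-1.38), BIRC5 (-1.35) and BCL2A1 lower. NOTCH pathway genes had 8 of 12 higher and 3 lower (adjusted p = 0.243), with NRARP (1.02) and DLL1 (0.72) higher and DTX1 (-1.67) and MAML3 (-0.75) lower.

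Of markers of other cell types, the stromal genes THY1 and DCN were expressed in SUDHL4 and fell there. The fibroblast and epithelial list had 3 measured genes, 2 lower and none higher on average (adjusted p = 0.29). THY1 fell from 28.4 ± 1.51 to 6.36 ± 0.743 FPKM and DCN from 25.4 ± 1.52 to 8.86 ± 0.950 FPKM in SUDHL4 (SD, n = 3), while in the other lines no library exceeded 1 FPKM. Of the monocyte markers CD14 rose by 0.91 on average (adjusted p = 2.82e-09), from means of 0.130, 0.105 and 0.0912 FPKM in DMSO to 1.18, 0.971 and 1.11 FPKM in SUDHL6, SUDHL4 and Farage. LYZ rose by 0.24 (adjusted p = 0.0335), a call that 9 of the runs without a single library and the run without the filter lost, with adjusted p from 0.00123 to 0.0725 over 29 alternatives. CD3E, the only T and NK cell marker measured, was listed at 0 in SUDHL6 and Farage. In SUDHL4 it was at 1.03, 1.13 and 1.05 FPKM in DMSO and at 0.540, 0.808 and 0.660 FPKM under the inhibitor (average -0.10, adjusted p = 0.00326). With a trend over GC content and transcript length removed, the CD3E average was 0.12 (adjusted p = 0.0256, with 0.000205 to 0.0277 over 29 alternatives). In SUDHL6 and Farage, where CD3E was at 0, its change in that run comes only from the subtracted trend. No mitochondrially encoded transcript was measured as a named gene. The mitochondrial chromosome was listed as 1 unnamed locus, at 1678, 1521 and 1872 FPKM in treated SUDHL4, at 2776 and 2425 FPKM in inhibitor and DMSO replicate 3 of SUDHL6, and at 0 in all other libraries.

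Over the 25 tested lists camera called 8 higher and 8 lower on average, and with an estimated correlation it called 0 higher and 0 lower. Besides glycolysis and hypoxia, immediate early genes and BCL6 targets, calls on average without a call within a line were the interferon list in SUDHL6 (adjusted p = 0.567) and SUDHL4 (0.588), aryl hydrocarbon receptor targets in SUDHL6 (0.0555), G2 and mitosis (0.0596) and MHC class II (0.328) in SUDHL4 and DNA damage in Farage (0.156). Of list members named by their average, HDAC9 (0.01, adjusted p = 0.985), BLM (-0.18, 0.55) and IRF7 (-0.30, 0.0703) did not pass the test in Farage. HIST1H4C (-0.23, adjusted p = 0.632) and IRF4 (0.99, 0.0545) did not pass it in SUDHL4, nor MAML3 in SUDHL6 (-0.17, 0.15). Fry, which tests whether a list moves on balance without comparing it with other genes, gave 14 higher and 9 lower. Adjusted over the list alone, the counts on average were those given except for DNA damage (3 higher, 19 lower), immediate early genes (17 higher, 5 lower) and MYC and ribosome biogenesis (0 higher, 18 lower).

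**Figure D2:**
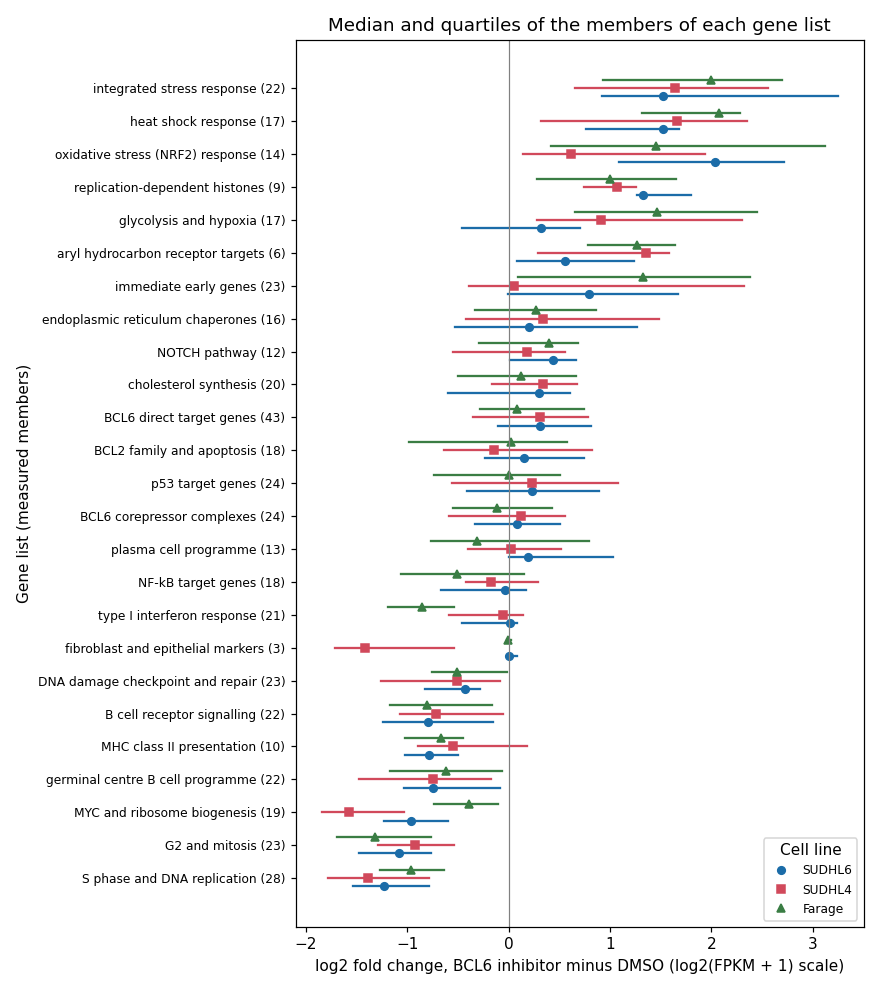
Log2 fold change, inhibitor minus DMSO on log2(FPKM + 1), of the members of 25 gene lists in SUDHL6, SUDHL4 and Farage. Points are the median of a list and bars its quartiles across genes. Medians of the heat shock list are 1.53, 1.66 and 2.08, those of the S phase list -1.23, -1.39 and -0.96.

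In SUDHL6 the surface receptor gene SLAMF7 rose most on log2(FPKM + 1), by 5.42, from 0.608 ± 0.0677 to 75.9 ± 47.3 FPKM (SD, n = 3, adjusted p = 3.04e-08). RGS1 (4.84), SQSTM1 (4.55), ATF3 (4.32) and LY9 (4.20) followed. These ranks depend on the pseudocount at low values, since OSGIN1, not among them, went from 0.0190 to 12.4 FPKM in this line. SIT1 fell most, from 96.3 ± 1.67 to 9.59 ± 4.87 FPKM (-3.34, adjusted p = 1.49e-07), followed by FAM81A (-3.08), the transcription factor CUX2 (-3.02), VPREB3 (-2.98) and ELL3 (-2.82). For each of these 10 genes all 3 treated libraries lay on 1 side of all 3 DMSO libraries, as the rule that named them requires. In total 3682 genes were higher (30.2%) and 4109 lower (33.7%).

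Stress lists rose in SUDHL6, with 18 of 22 integrated stress response genes higher (adjusted p = 2.6e-07, and 0.331 as the adjusted p with an estimated correlation). Likewise 14 of 17 heat shock genes were higher (adjusted p = 1.19e-05, and adjusted p = 0.342 with an estimated correlation) and 11 of 14 NRF2 response genes (adjusted p = 0.000112, and adjusted p = 0.331 with an estimated correlation). The BCL6 targets were called here, with 22 higher and 7 lower of 43 (adjusted p = 0.0219, and adjusted p = 0.331 with an estimated correlation). S phase genes fell in 24 of 28 cases, 25 when adjusted over the list alone (adjusted p = 0.000145, and adjusted p = 0.541 with an estimated correlation), and MYC and ribosome biogenesis genes in 18 of 19 (adjusted p = 6.48e-06, and adjusted p = 0.331 with an estimated correlation). Camera called 6 lists higher and 7 lower in this line, and 0 of either with an estimated correlation. Both replicate 3 libraries of SUDHL6 listed 0 of 244 loci under 80 bp above 0, where the other 16 libraries listed 28 to 37. The treated libraries spread widely in induced genes, with RGS1 at 334, 161 and 100.7 FPKM in replicates 1, 2 and 3. With the replicate number as a block 3888 genes were higher and 4417 lower.

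In SUDHL4 the largest increases were those of PPP1R15A (4.59), which encodes the stress-induced phosphatase subunit GADD34, RGS1 (4.46), SLC7A11 (4.13), DDIT3 (4.05) and HSPA1B (3.99). PPP1R15A went from 16.8 ± 17.3 to 326 ± 86.6 FPKM (SD, n = 3, adjusted p = 5.65e-07). PTPN6 fell by 3.53 on the log2 scale (adjusted p = 3.95e-08), and the oncogene MYC, on chromosome 8 from 128747400 to 128754863, fell by 3.51, from 146 ± 17.2 to 11.8 ± 0.480 FPKM (adjusted p = 1.71e-11). MRPS26 (-3.04), FAM111B (-2.95) and the uracil glycosylase UNG (-2.92) completed the 5 largest decreases. Each had all 3 treated libraries below all 3 DMSO libraries, as the rule that named them requires. The counts were 3616 higher (29.6%) and 4525 lower (37.1%).

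Among SUDHL4 lists the integrated stress response had 17 of 22 genes higher (adjusted p = 3.28e-06, and adjusted p = 0.417 with an estimated correlation), and heat shock 14 of 17 (adjusted p = 1.13e-05, and adjusted p = 0.417 with an estimated correlation). Glycolysis and hypoxia genes had 12 of 17 higher and 1 lower (adjusted p = 0.000246, and adjusted p = 0.417 with an estimated correlation). MYC and ribosome biogenesis genes fell in 15 of 19 cases with a median of -1.57 (adjusted p = 3.28e-06, and adjusted p = 0.417 with an estimated correlation). S phase genes fell in 24 of 28 cases, 25 when adjusted over the list alone (adjusted p = 0.000108, and adjusted p = 0.589 with an estimated correlation). Camera called 6 lists higher and 5 lower, and 0 of either with an estimated correlation. DMSO replicate 3 held part of the induced levels, as in PPP1R15A at 6.91, 6.82 and 36.8 FPKM in DMSO replicates 1 to 3. Without it PPP1R15A rose by 5.34, RGS1 by 5.16, SLC7A11 by 4.85, DDIT3 by 4.72 and HSPA1B by 4.58, and 3484 genes were higher and 4372 lower.

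In Farage HMOX1 rose from 26.5 ± 0.929 to 1098 ± 54.1 FPKM (SD, n = 3), a log2 fold change of 5.32 (adjusted p = 1.78e-09). HSPA1B (4.91), HSPA1A (4.46), OSGIN1 (4.36) and the decoy death receptor TNFRSF10D (4.29) followed. MPEG1 fell most (-3.35), from 101 ± 3.77 to 9.02 ± 0.358 FPKM (adjusted p = 6.25e-09), before SNX22 (-3.05), VPREB3 (-3.01), CUX2 (-2.99) and HLA-DMB (-2.95). All 3 treated libraries lay beyond all 3 DMSO libraries for each of the 10, as the rule that named them requires. The counts were 3564 higher (29.2%) and 4631 lower (38%).

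All 17 heat shock genes rose in Farage (adjusted p = 3.65e-09, and adjusted p = 0.283 with an estimated correlation), as did 21 of 22 integrated stress response genes (adjusted p = 3.65e-09, and adjusted p = 0.169 with an estimated correlation) and 17 of 23 immediate early genes (adjusted p = 1.47e-05, and adjusted p = 0.172 with an estimated correlation). Interferon response genes fell in 15 of 21 cases and rose in 0, the same counts when adjusted over the list alone, and this call alone held with an estimated correlation (adjusted p = 7.5e-05, and adjusted p = 0.012 with an estimated correlation). IFI35 fell from 15.8 ± 0.600 to 2.92 ± 0.603 FPKM (-2.11). G2 and mitosis genes fell in 19 of 23 cases (adjusted p = 0.0102, and adjusted p = 0.799 with an estimated correlation) and S phase genes in 21 of 28 (adjusted p = 0.00938, and adjusted p = 0.799 with an estimated correlation). Camera called 7 lists higher and 7 lower. Across the lines, median, mean and camera direction differed in sign only in lists without a call, such as the interferon list in SUDHL6 (median 0.01, mean -0.08, direction down) and the plasma cell list in Farage (median -0.31, mean 0.09, direction up).

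The lines shared most of their calls in direction and differed in size and, for some genes, in sign. In SUDHL6 and SUDHL4, 2739 genes were called higher and 3127 lower in both, where lists independent of each other would share 1091.2 and 1523.9. SUDHL6 and Farage shared 2606 higher and 3067 lower (1075.5 and 1559.6 for independent lists), and SUDHL4 and Farage 2575 and 3288 (1056.3 and 1717.5). Opposite calls were made for 292 of 6158, 355 of 6028 and 388 of 6251 genes called in both lines of these pairs. Pearson's r of the log2 fold changes across genes was 0.669, 0.645 and 0.633 and Spearman's rho 0.755, 0.713 and 0.723, given as descriptions since genes are not independent replicates. In all 3 lines 2231 genes were higher and 2581 lower, and 738 genes were called higher in at least 1 line and lower in another.

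The response differed between lines for 6403 genes (52.5%) by the F test, of which 3818 had effects of a single sign in the 3 lines and the others did not. MYC fell in SUDHL6 from 128 ± 3.71 to 52.2 ± 5.76 FPKM and in SUDHL4, and was at 67.9 ± 3.67 and 62.7 ± 6.53 FPKM in Farage (-0.12, adjusted p = 0.303), with a difference between lines at adjusted p = 8.09e-10. HMOX1 rose in SUDHL6 (3.85) and Farage and had 0.239 ± 0.0442 and 0.415 ± 0.0603 FPKM in SUDHL4 (0.19, adjusted p = 0.585, difference 6.48e-07). The 6 genes with the smallest p of the difference moved most in Farage. There G0S2 (2.70), the secreted factor STC2 (2.48), the nuclear receptor NR4A2 (2.72) and HSPA1A rose, and the interferon-induced GTPase GBP1 (-1.68) and UNQ6494 (-2.72) fell. HSPA1A also rose in SUDHL6 from 0.381 to 3.45 FPKM (1.68, adjusted p = 2.96e-09) and in SUDHL4 from 0.0331 to 0.285 FPKM (0.32, adjusted p = 0.00236). G0S2 was listed at 0 in all 6 libraries of SUDHL6 and of SUDHL4 and at 0.447, 0.439 and 0.370 FPKM in Farage DMSO against 8.35, 8.67 and 7.71 FPKM under the inhibitor. GBP1 and UNQ6494 were listed at 0 in all SUDHL6 libraries and reached at most 0.0958 and 0.06725 FPKM in SUDHL4. STC2 and NR4A2 reached at most 0.07061 and 0.1102 FPKM in the libraries of SUDHL6 and SUDHL4. For these genes and G0S2 the difference goes with values near 0 outside Farage. The interferon list fell more in Farage (median -0.86) than in SUDHL6 (0.01, adjusted p = 5.56e-07, and adjusted p = 0.00156 with an estimated correlation) and than in SUDHL4 (-0.06, adjusted p = 6.06e-06, and adjusted p = 0.00264 with an estimated correlation). IFI35 had 2.02 and 3.32 FPKM in DMSO of SUDHL6 and SUDHL4, and with a pseudocount of 0.1 its log2 fold change was -2.41 in Farage, -2.30 in SUDHL6 and -1.24 in SUDHL4. With that pseudocount the list medians were -0.99 in Farage, 0.10 in SUDHL6 and -0.44 in SUDHL4. The difference from SUDHL6 had adjusted p = 0.00186 (adjusted p = 0.0407 with an estimated correlation), and that from SUDHL4 adjusted p = 0.00813 (adjusted p = 0.0891 with an estimated correlation).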

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

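The tests of a library batch for the SUDHL6 replicate 3 libraries, both tests of SUDHL4 DMSO replicate 3 the tests of list differences between lines and the runs of differences with a pseudocount of 0.1 were chosen only after the result was seen.

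Of the 120 named genes 55 differed between lines in the F test of the difference itself, as did 6403 of all tested genes. For 53 of the 55 the value given is the largest minus smallest log2 fold change of the 3 lines on log2(FPKM + 1). It depends on the pseudocount where a line has values near 0: with a pseudocount of 0.1, 5 of the 53 moved by over 1.5 times, to 0.62 for CD3E, 1.79 for DLL1, 3.80 for CCR7, 6.35 for HIST1H4C and 4.72 for CCL3, while TNFRSF10D had 3.25 and HSPA1A 3.35. With it 47 of the 53 still passed the F test, and PTPN6 (adjusted p = 0.165), FCGR2B (0.582), MPEG1 (0.0866), DNAJB1 (0.0556), NBN (0.0528) and DUSP5 (0.0518) did not. Stress and signalling genes were HMOX1 (5.13), HSPA1A (4.15), TNFRSF10D (3.90), NR4A2 (2.76), G0S2 (2.70), RGS1 (2.47), STC2 (2.47), HSPA1B (2.04), P4HA1 (1.98), SLC7A5 (1.83), BNIP3L (1.58), DUSP5 (1.57), SEL1L (1.56), VEGFA (1.47), SRXN1 (1.35), CYP1B1 (1.32), SESN2 (0.88) and DNAJB1 (0.81). Growth, replication and repair genes were MYC (3.39), FAM111B (1.98), UNG (1.78), BLM (1.70), MRPS26 (1.30), AEN (1.17) and NBN (0.35). Genes of B cells, immune signalling and antigen presentation were SLAMF7 (3.26), CCL3 (3.15), CCR7 (2.49), MPEG1 (2.24), IRF7 (1.94), GBP1 (1.76), HLA-DMB (1.60), CIITA (1.57), VPREB3 (1.48), PTPN6 (1.23), IFI35 (1.23), CXCR4 (1.01), BLNK (1.01) and FCGR2B (0.45). BCL6 itself differed by 1.05, HDAC9 by 1.8, SKP1 by 0.81, DTX1 by 1.00, MAML3 by 0.98 and DLL1 by 0.95. The remaining genes were HIST1H4C (4.15), UNQ6494 (2.75), CUX2 (2.69), FAM81A (2.17), THY1 (2.00), SNX22 (1.62), DCN (1.47) and CD3E (0.31).

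Camera on the difference of the responses, with its adjusted p, placed log2 fold changes higher in SUDHL4 than in SUDHL6 for glycolysis and hypoxia (3.57e-06), endoplasmic reticulum chaperones (0.0226) and MHC class II (0.0339), and lower for fibroblast and epithelial markers (0.0226) and MYC and ribosome biogenesis (0.0306). They were higher in Farage than in SUDHL6 for glycolysis and hypoxia (9.37e-08), heat shock (0.000257), immediate early genes (0.000318), MYC and ribosome biogenesis (0.00447) and aryl hydrocarbon receptor targets (0.0214), and lower for the interferon response (5.56e-07) and p53 targets (0.0392). They were higher in Farage than in SUDHL4 for immediate early genes (3.82e-05), MYC and ribosome biogenesis (3.82e-05), fibroblast and epithelial markers (0.0338) and heat shock (0.0351), and lower for the interferon response (6.06e-06). With an estimated correlation the interferon differences held (0.00156 and 0.00264), and the other 15 of these 17 did not, with adjusted p from 0.197 to 0.876. With a pseudocount of 0.1, 15 of the 17 stayed past the threshold, without the aryl hydrocarbon receptor targets (0.0513) and p53 targets (0.056). With an estimated correlation as well, the interferon difference of Farage from SUDHL6 held (0.0407) and that from SUDHL4 did not (0.0891). Of 1075 unnamed loci that passed the filter, which no comparison above uses, 288 were higher and 310 lower on average under the inhibitor.

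For the count of the average, 1 of 100 splits of the samples within lines, the real one, gave as many genes. It gave 9831 genes against 5327 in the highest other split. That other split mixed the labels of SUDHL4 only and left SUDHL6 and Farage as labelled, so it kept much of the real response. The 69 splits that mixed the labels of all 3 lines gave at most 4 genes. A share of 1 in 100 is the lowest 100 splits can give, and it argues against a chance split of the libraries. Whether replicates were separate cultures is not known, so chance differences between cultures are not covered. For the difference between lines, 2 of 100 splits gave as many genes, with 7224 in the highest other split against the real 6403. These splits test no response at all, not an equal response in the 3 lines, so they decide nothing on that difference. The split with 7224 genes exchanged all SUDHL6 labels and left Farage as labelled, which by itself sets the response of SUDHL6 against that of Farage. Within a line 3 against 3 make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave the most: 7791 genes in SUDHL6 against 179 in the highest other, 8141 in SUDHL4 against 0 and 8195 in Farage against 1.

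The breadth of the averaged response, 9831 of 12201 genes, was set against trends of the libraries. Removing a trend over GC content and transcript length per library left 89.6% of the called genes with an annotation called with the same sign (7635 of 8520), which argues against such a trend as the whole cause. Median-ratio scaling kept 98.2% and quantile normalization 94.2% of the calls with their sign, which argues against scaling between libraries. The inhibitor may account for the breadth. But relative depth, where it could be read, was lower in every treated than in every DMSO library within each line and so goes with the treatment. The Farage groups were apart by less than 0.02 at their nearest. Neither depth nor a change in total RNA per cell was tested as a cause.

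The SUDHL6 replicate 3 libraries stand apart, on the fourth principal component (7.2% of the variance) at -65.93 for the inhibitor and -58.17 for DMSO. A mislabelled cell line is argued against, since each correlated best with its own line and treatment, by a margin of at least 0.05 over any group of another line, and so is an exchange of the treated and DMSO labels, since the replicate 3 difference correlated at 0.663 across genes with that of replicates 1 and 2. A library or read length batch may be the source, as 0 of 244 loci under 80 bp had a value above 0 in either library, where the other 16 libraries had 28 to 37. The mitochondrial locus was above 0 in both (2776 and 2425 FPKM) and in the 3 treated SUDHL4 libraries (1678, 1521 and 1872 FPKM) and at 0 in all others, so it sets them apart within their line but not from all libraries. No biological explanation was tested, and a separate culture on another day stays open.

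SUDHL4 DMSO replicate 3 lies toward the treated libraries. Over 26 genes nearly off in the other DMSO libraries of SUDHL4 it held a median fraction of 0.11 of the treated level (quartiles 0.1 and 0.123). The 121 fallen genes were lowered by a median fraction of 0.174 (quartiles 0.135 and 0.225). The relative spread of the fraction over the 26 risen genes in SUDHL4 DMSO replicate 3 was 0.152, within that among treated libraries (0.0688 to 0.29). RNA, cells or reads of treated SUDHL4 samples mixed in may be the source. A mixture at 1 even fraction would give risen and fallen genes the same fraction, however, and their quartiles did not overlap. Lowered fallen genes were also seen without risen ones, in SUDHL6 DMSO replicate 1 (median fractions 0.32 and 0.00222), so they are weak support for a mixture. Reads from treated libraries of another line are argued against, since genes that rise there and not in SUDHL4 reached a fraction of 0.00394 at most. An even response of a part of that culture, with no admixture, stays open and was not tested. The mitochondrial locus was at 0 in this library and at 1521 to 1872 FPKM in the treated ones. It was also at 0 in the other DMSO libraries of the line and in all Farage libraries. A 0 there may therefore not mean absence, and this single locus decides nothing on a mixture.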

How the results depend on the processing

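The runs without both SUDHL6 replicate 3 libraries, without small RNA loci, with unnamed loci, with the GC and length trend removed, the estimated correlation with a block or without those libraries, and the F test of named genes with a pseudocount of 0.1 were chosen only after the result was seen. Of the 159 results on the 120 named genes all kept direction and side of the threshold under a pseudocount of 0.1, median-ratio scaling, quantile normalization, limma without trend, limma robust, without both SUDHL6 replicate 3 libraries, without small RNA loci and with unnamed loci. The block moved 2 of them, both of BCL6, and the unfiltered run moved 1, LYZ. Of 2862 results with a library left out 2852 kept their call, and the others were 9 of LYZ and 1 of BCL6. The F test of the difference between lines kept 47 of 53 named genes past the threshold with a pseudocount of 0.1. CD3E reversed to 0.119 (adjusted p = 0.0256, with 0.000205 to 0.0277 over its alternatives) with the GC and length trend removed. It was listed at 0 in SUDHL6 and Farage, so its change there after that step comes only from the subtracted trend. The reversal is thus no rise of its transcript.

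With a mean of at least 5 FPKM fewer genes were tested, and 3561 were lower on average and 4229 differed between lines. With an absolute log2 fold change of at least 0.5, a stricter criterion, the average had 2442 higher and 3224 lower. Camera called 0 lists higher and 0 lower with an estimated correlation. With that estimate it also called 0 and 0 with the block, and 0 and 0 without both SUDHL6 replicate 3 libraries. The estimate allows for genes of a list that vary together. It was 0.92 for G2 and mitosis, but 0.016 for BCL6 targets and -0.028 for the interferon list. Calls of lists with such low estimates were lost too, but only in the adjustment over the lists. Before it, camera p went from 0.0144 to 0.0429 for BCL6 targets. For the interferon list it went from 0.0107 to 0.0162, so both stayed under 0.05. Fry, which does not compare a list with other genes, gave 14 higher. The other counts stayed within 1.5 times under each alternative run.

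With 1 library left out at a time, the average ran from 4266 to 4435 higher and from 5361 to 5575 lower, and the difference from 5759 to 7039. SUDHL6 ran from 3437 to 3716 higher and from 3825 to 4264 lower, SUDHL4 from 3375 to 3787 and from 4158 to 4699, and Farage from 3328 to 3714 and from 4299 to 4844. With the block, the average had 4529 higher and 5631 lower and the difference 7234. Scaling moved the median log2 fold change of all genes from -0.08 to -0.05 and -0.02. Depth in counts is unknown, so how far it limits genes with low values was not assessed.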

Other observations

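The tests of the added lists were chosen only after the result was seen, and that of the BCL6 targets held by no other list was not.

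Of 30 lysosomal genes 24 rose and 3 fell on average over the 3 lines, among them the sialidase NEU1 (2.48), the acid ceramidase ASAH1 (2.38), GLA (2.31) and the membrane protein LAMP1 (1.74), with a median of 0.99 (adjusted p = 2.27e-06, and adjusted p = 0.234 with an estimated correlation). LAMP1 went from 41.4 ± 5.10 to 109 ± 12.7 FPKM in SUDHL6, from 36.2 ± 11.9 to 219.9 ± 21.7 in SUDHL4 and from 42.4 ± 1.61 to 99.9 ± 1.40 in Farage (SD, n = 3). Of 26 autophagy genes 22 rose and 3 fell, with SQSTM1, GABARAPL1 (3.36), FNIP2 (2.66) and MAP1LC3B (2.49) rising most and a median of 0.76 (adjusted p = 2.27e-06, and adjusted p = 0.169 with an estimated correlation). SUDHL4 DMSO replicate 3 lay above the other DMSO libraries for SQSTM1, at 88.4 FPKM against 23.8 and 25.2.

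Of 63 mitochondrial ribosomal protein genes 52 fell and 8 rose, with MRPS34 (-2.27), MRPS26 (-2.19), MRPL27 (-1.74) and MRPL17 falling most and a median of -0.44 (adjusted p = 4.02e-06, and adjusted p = 0.374 with an estimated correlation). Of 31 subunits of respiratory complex I 27 fell and 0 rose, with NDUFB7 (-1.54), NDUFV1 (-1.36) and NDUFS7 (-1.35) and a median of -0.56 (adjusted p = 7.57e-06, and adjusted p = 0.261 with an estimated correlation). Tubulins and actins had 13 of 16 lower and 1 higher, with TUBB (-2.21) and ACTB (-1.39) and a median of -0.74, or -0.70 and -0.69 under the other 2 scalings (adjusted p = 0.00226, and adjusted p = 0.239 with an estimated correlation). Cytosolic ribosomal protein genes had 21 of 53 higher and 2 lower with a median of 0.12, which turned to -0.02 under quantile normalization (adjusted p = 0.0239, and adjusted p = 0.754 with an estimated correlation). The proteasome list gave no call, with 15 of 31 higher and 11 lower (adjusted p = 0.276).

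A hypothesis is that lysosome genes and autophagy genes each rise as a set under the inhibitor. Camera on the averaged contrast gave adjusted p = 2.27e-06 for lysosome genes and 2.27e-06 for autophagy genes, and adjusted p = 0.234 and 0.169 with an estimated correlation, so the hypothesis may hold only as far as the preset correlation does. That mitochondrial ribosomal protein genes fall as a set was tested in the same way, with adjusted p = 4.02e-06, and adjusted p = 0.374 with an estimated correlation. Both were noticed and tested in the same libraries.

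A further question was whether the rise of the BCL6 direct targets rests on members shared with the other fixed lists. The 18 of 43 members that no other fixed list holds gave p = 0.000603 for a rise (p = 0.0761 with an estimated correlation), with 12 higher, 0 lower and a median log2 fold change of 0.61, against 0.16 for the 25 shared members. With the preset correlation this argues against shared members as the source of the rise, and with the estimated correlation the test does not decide. The unshared members may include direct targets, which binding data, not used here, would be needed to test.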
